A study of Mus musculus with 17 samples.

How the data were processed

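Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on crosslinked epidermal cells of female mice, with an antibody against the histone mark H3K27ac and an antibody against UTX, the protein made by Kdm6a. Control mice had Kdm6a flanked by loxP sites and no Cre recombinase. Utx-deleted mice carried the same alleles and Cre. The labels hold 17 libraries: 3 UTX, 2 H3K27ac and 3 input libraries of control mice, and 3 of each kind of Utx-deleted mice. The groups were taken from the sample labels. The number in a library title was read as the animal, which the labels do not state. On that reading the antibodies and the input share 3 animals within a genotype, and 2 of the control animals gave H3K27ac libraries. Per the labels' protocols each group has 3 samples, whereas the labels hold 2 control H3K27ac libraries, and whether the merged control list includes a further library is not known.

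The authors deposited 4 peak lists, 1 for each antibody and genotype, and each line holds a chromosome, a start and an end. Per the file headers, the peaks were called with MACS2 on the merged data of all samples of a group. Bowtie2, bedtools, deepTools and FastQC are named per the submitters' processing notes, with no version. A list therefore has no replicates, and no test between genotypes and no removal of single libraries was possible. The lists as used here hold no height, fold enrichment or q, so peaks were ranked by width, and a stricter q was not tried. Read depth per library is unknown from the lists, and peak numbers rest on libraries whose depth may differ. The input libraries were not analysed here as separate values.

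The processing notes name both mm10/GRCm38 and mm39/GRCm39. The build was settled from the positions. Of the control H3K27ac peaks, 32.9% lay within 1 kb of an end of a protein-coding gene of GRCm38, against 8.41% and 8.88% when the peaks were moved by 10 kb in either direction. Coordinates are 1-based and on GRCm38. The annotation used here gives the start and end of 21887 protein-coding genes, without strand, exons or a genome sequence. The promoter, exon and intron classes planned at first were therefore replaced by 3 classes: within 1 kb of either end of a gene, inside a gene, and intergenic. Each peak was assigned to the gene it lies in or, outside genes, to the nearest gene. The 6 peaks on unplaced sequence were left out of analyses that need genes or chromosome lengths.

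Peaks were called shared when they overlapped by at least 1 bp. Overlap was set against 1000 random placements of the peaks on their own chromosomes, with a one-sided p, whose smallest possible value is 0.001. The two-sided p of the location classes cannot go below 0.002. Repeats and gaps of the genome were not masked in the placements. Gene-level overlap and 19 gene lists were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment, and with 10000 draws of genes matched on gene length in 10 bins. Peaks per chromosome were tested with an exact binomial test, two-sided, against chromosome length. Widths were compared with 100000 permutations, two-sided. Intervals of shares are Wilson 95% intervals and cover counting error only. Peaks that lie close together are not independent, so tests over peaks give p-values that are too small where peaks cluster.

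The gene lists, most tests, the alternatives tried and the rule for named genes were set before the data were examined. The width comparison of shared and other UTX peaks and the random placement of the location classes were not in that plan. Alternatives added later are marked as such. Named genes are those of the 8 widest peaks of each list, up to 20 genes with a peak in both control lists, up to 10 with a peak in both genotypes, up to 4 members of each gene list by width, Kdm6a, and any gene of a list with at most 30 genes. Genes named outside this rule were chosen after their values were seen, and some genes that the rule names are not reported here. The alternatives were the wider peaks only, other overlap rules, merged peaks, chromosomes 1 to 19, other distances, gene assignments, backgrounds and random placements.

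The procedures were tested on simulated data before use. With 20 of the 547 control UTX peaks moved onto H3K27ac peaks, the overlap was called in 50 of 50 runs, and in 1 of 50 runs with none moved. A list of 40 genes with 10 planted members, over 21887 genes, was called in 200 of 200 runs, and a list with none planted in 9 of 200. The other peaks were placed, and the other genes drawn, at random, so these runs do not cover clustering of peaks or genes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.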

Results

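H3K27ac, a mark of active promoters and enhancers, and UTX, a histone H3K27 demethylase and subunit of the COMPASS-like complexes, were mapped in mouse epidermis with and without Kdm6a. The control H3K27ac list held 2140 peaks from 2 labelled libraries, covering 685569 bp, and the Utx-deleted H3K27ac list held 48 peaks from 3 libraries, covering 16094 bp. The control UTX list held 547 peaks covering 163380 bp and the Utx-deleted UTX list 213 peaks covering 68400 bp, from 3 libraries each. Median widths were 273, 296, 328 and 289 bp in that order. Each list was called on merged libraries, so no value has a replicate error and no difference between genotypes could be tested against replicate spread. Kdm6a itself, on chromosome X from 18160862 to 18279936, had no peak assigned to it in any of the 4 lists.

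The first comparison asks where the epidermis carries H3K27ac. In control epidermis the peaks were assigned to 1306 genes. Gata3, a transcription factor of epidermal and hair follicle differentiation, was assigned 19 peaks. Dsp, which encodes desmoplakin of the desmosome, was assigned 11. Tnfaip3, a feedback inhibitor of NF-kB, was assigned 12 peaks and the tetraspanin gene Cd9 10. Peaks outside genes count for the nearest gene at any distance. Of the 19 Gata3 peaks, 0 lay within 1 kb of an end of that gene. The widest Tnfaip3 peak lay 45505 bp outside its gene. The widest peak, of 1798 bp, lay inside Clec2g on chromosome 6 from 128972361 to 128974158. The next widest lay inside Skint1 (1292 bp, chromosome 4, 112008513 to 112009804), 31101 bp outside Tuba1a (1228 bp) and at an end of Hcar2, a receptor for hydroxy-carboxylic acids (1171 bp). Wide peaks also lay outside Chd2 (1119 bp) and Krt80 (1015 bp).

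Of the 19 gene lists, 6 had more genes with a control H3K27ac peak than expected. Among AP-1 transcription factors, 11 of 20 genes had a peak, against 1.19 expected (odds ratio 19.4, adjusted p = 6.343e-08, Fisher's exact test). Fosb, Mafk, Atf4 and Fosl2 were among them, and the nearest Fosb peak lay 9416 bp outside the gene. Of 40 transcription factors of epidermal differentiation, 11 had a peak (odds ratio 6.02, adjusted exact p = 9.614e-05), with 5 peaks at Tfap2a, 6 at Grhl3 and 2 at Klf4, which acts in barrier formation. Of 40 basal keratinocyte genes, 10 had a peak (odds ratio 5.29, adjusted exact p = 4.287e-04). The named members of that list were junction and adhesion genes: Dsp, Jup with 7 peaks, Pkp3 with 3 and the hemidesmosome gene Col17a1 with 2. Krt5, Krt14, Krt15, Trp63, Itga6 and Itgb4, also in that list, had no peak assigned.

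The cornified envelope list had 11 of 72 genes with a peak (odds ratio 2.86, adjusted exact p = 0.0109). Krt80 was assigned 6 peaks, the nearest 11914 bp outside the gene, and Sprr2a1 was assigned 2, the nearest 3677 bp outside. Spink5, an inhibitor of epidermal proteases, had 2. Sprr2a2, which also had a peak, lies close to Sprr2a1 on chromosome 3, and neighbouring genes are not independent. Flg, Ivl and Krt1 had no peak assigned. The barrier lipid list had 8 of 42 (odds ratio 3.72, adjusted exact p = 0.0109), with 5 peaks at the lipid transporter gene Abca12 and 2 at the lipoxygenase gene Aloxe3. Housekeeping genes were also over-represented, with 10 of 30 (odds ratio 7.93, adjusted exact p = 5.251e-05), among them B2m, Hspa8 and Actb. With the wider peaks only, the odds ratio of the cornified envelope list was 2.63 (adjusted exact p = 0.129) and that of the barrier lipid list 3.04 (adjusted exact p = 0.163).

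Retinoid genes did not pass, with 4 of 52 (Rara, Rarg, Crabp2 and Ncoa2; odds ratio 1.31, adjusted exact p = 0.806). Of the hair follicle list 5 of 76 had a peak, of the sebaceous list 4 of 30, of the wound list 2 of 35, of the UTX, COMPASS-like and Polycomb list 4 of 35 (with 4 peaks at Kdm6b, a related demethylase), of the ferroptosis list 2 of 33 and of the cell cycle list 4 of 35. None of these passed (adjusted p from 0.274 to 1). Markers of other cell types gave 0 of 31 immune, 0 of 26 fibroblast, 0 of 13 melanocyte, 0 of 12 Merkel cell and 0 of 10 erythroid genes. Expected were 1.85, 1.55, 0.776, 0.716 and 0.597, so few that even 0 could not be called lower than the share over all genes (unadjusted exact p from 0.259 to 1). Of 22 endothelial, mural and muscle genes, 2 had a peak: Pecam1 with 6 and Vwf with 1 (adjusted exact p = 0.637).

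**Figure D1:**
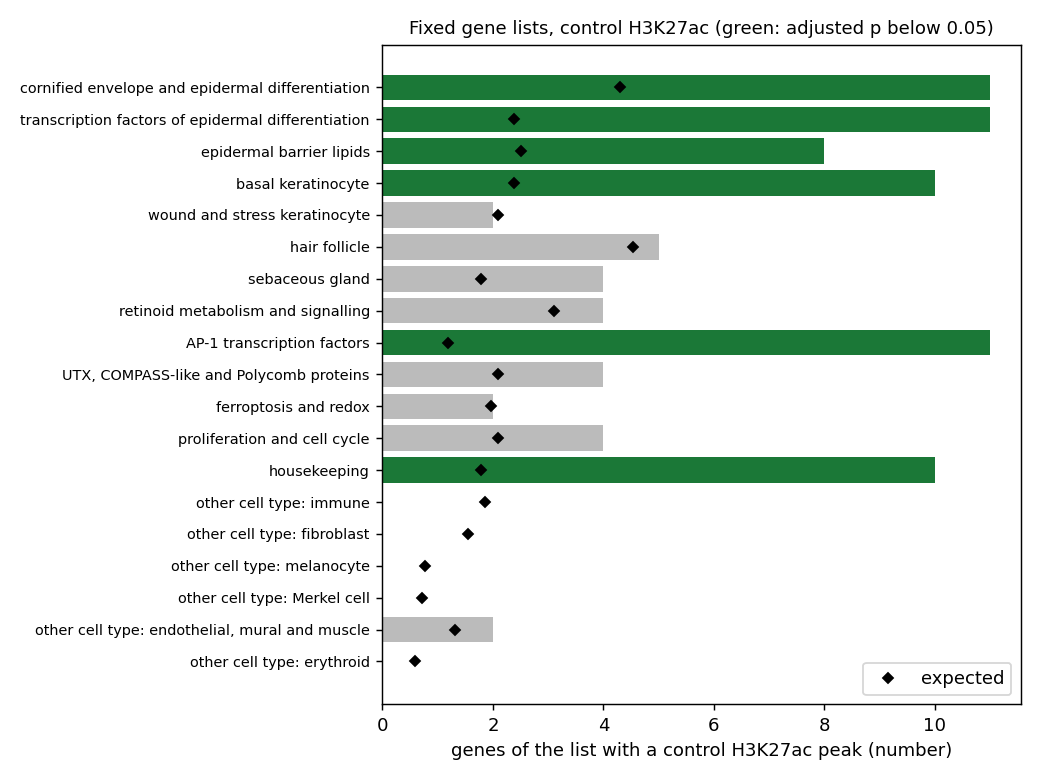
Genes of each list with a control H3K27ac peak (bars, number of genes) and the number expected from all protein-coding genes (diamonds). Green bars are the 6 lists with an adjusted p below 0.05, and AP-1 has 11 genes against 1.19 expected.

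Control H3K27ac peaks lay near gene ends more often than random placement gave, though most lay elsewhere, and were rare on the X chromosome. Of the placed peaks, 705 of 2139 (33.0%, 31.0 to 35.0) lay within 1 kb of a gene end, against 3.37% at random (two-sided permutation p = 0.002, the smallest the placements allow). A further 40.9% lay inside genes and 26.2% were intergenic. Chromosome X held 5 peaks where its length gave 139.8 (adjusted p = 3.418e-53, exact binomial test) and its genes 95.5 (adjusted p = 1.529e-33). Chromosome 11 held 261 peaks against 99.8, chromosome 19 held 138 against 47.7 and chromosome 14 held 37 against 102.1. By their genes 159.1, 69.7 and 84.2 peaks were expected on these chromosomes, so that the ratio for chromosome 11 was 2.61 by length and 1.64 by genes.

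The second comparison asks how H3K27ac peaks differ after Utx deletion. The Utx-deleted list held 44.6 times fewer peaks than the control list. Of the 2140 control peaks, 1 overlapped a Utx-deleted peak (random mean 0.023, one-sided permutation p = 0.024). It was assigned to Arid1b, a chromatin remodelling gene, and lay at a position with a peak in all 4 lists. The widest of these, the control UTX peak on chromosome 17 from 4626017 to 4626736, lay 367560 bp outside the gene. Genes with a peak in both genotypes were Arid1b and Pdia4, 2 against 1.61 expected (Fisher's exact p = 0.675). Within 1 kb the single shared peak no longer exceeded chance (permutation p = 0.0869).

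The 27 genes with a Utx-deleted H3K27ac peak were led by Zfp982, a zinc finger gene with 6 peaks. Gm42346 had 4, 4932411N23Rik on chromosome X had 4, and Snrpe had 3. The widest lay inside Dock2 (831 bp, chromosome 11, 34681641 to 34682471, and 695 bp) and Cldn34d (677 bp). Chromosome 4 held 21 of the 48 peaks, against 2.87 expected (adjusted p = 1.907e-12, exact binomial test). Within 1 kb of a gene end lay 6 of 48 (12.5%, 5.86 to 24.7), 4.16 times the random share (two-sided permutation p = 0.00999). This ratio was 2.63 within 500 bp (permutation p = 0.36) and 3.18 for the 19 peaks outside the 5 densest windows (p = 0.248), where it no longer passed the threshold.

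**Figure D2:**
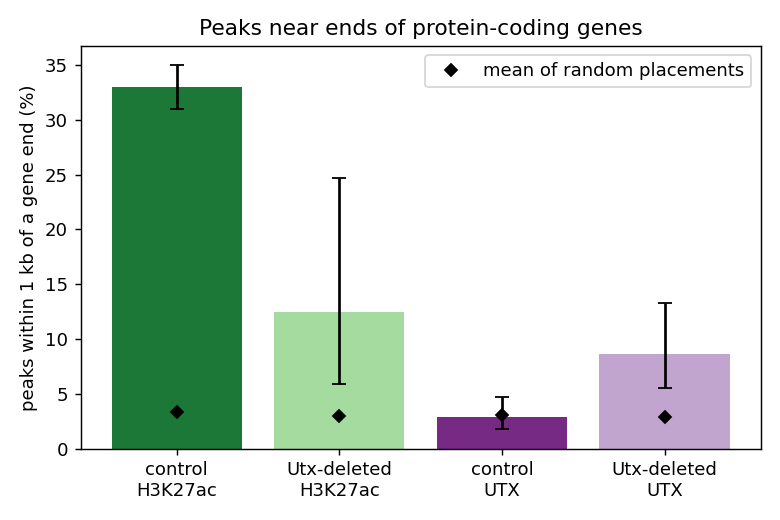
Share of peaks within 1 kb of an end of a protein-coding gene (bars, percent, with Wilson 95% intervals) in each list, and the mean of random placements (diamonds). Control H3K27ac stands at 33.0% and control UTX at 2.93%.

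The third comparison asks where the UTX antibody gave peaks and which of them remained after deletion. Control UTX peaks were assigned to 532 genes, of which 14 had 2 or more. The widest lay outside Arid1b (720 bp), outside Malt1, a signalling protease gene (651 bp, chromosome 18, 65427315 to 65427965), 142928 bp outside 1700066M21Rik (621 bp), inside Ncoa1, a nuclear receptor coactivator gene (600 bp, chromosome 12, 4417573 to 4418172) and at an end of Rps29 (586 bp). Ncoa1 had 3 peaks. Of the control UTX peaks, 16 of 547 (2.93%, 1.81 to 4.70) lay within 1 kb of a gene end, and random placement gave 3.04%. Inside genes lay 46.6%, against 38.1% at random (permutation p = 0.002, the smallest possible).

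None of the 19 gene lists was over-represented in the control UTX list (Fisher's exact test, Benjamini-Hochberg). Retinoid genes had 2 of 52 members with a peak, Ncoa1 and Rdh10. Melanocyte genes had 2 of 13, Tyrp1 and Oca2 (unadjusted exact p = 0.0385, adjusted p = 0.732), and this was the only list with an unadjusted p under 0.05. The AP-1, basal keratinocyte and cornified envelope lists had 0 of 20, 0 of 40 and 0 of 72, where 0.486, 0.972 and 1.75 were expected (unadjusted exact p = 1, 1 and 0.425). With 112 genes in the Utx-deleted UTX list and 27 in the Utx-deleted H3K27ac list, at most 0.389 and 0.0938 members of a gene list were expected, too few to compare these lists with the control.

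Of the 547 control UTX peaks, 71 (13.0%, 10.4 to 16.1) overlapped a Utx-deleted UTX peak, against 0.025 at random (permutation p = 0.001, one-sided, the smallest possible). They made up 33.3% of the 213 Utx-deleted peaks, and 72 genes had a peak in both lists. Among these were Arid1b, Malt1, Ncoa1, Rps29, Nemf, Alox5ap and Ano2, the genes of 7 of the 8 widest control peaks. The remaining gene, 1700066M21Rik, had no Utx-deleted UTX peak. In the control list the shared peaks had a median width of 371 bp and the others 301.5 bp (permutation p = 0.0166, a comparison not planned). In width classes set after the widths were seen, 22 of 24 peaks of 380 bp or more were shared, and 1 of 194 peaks under 240 bp.

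**Figure D3:**
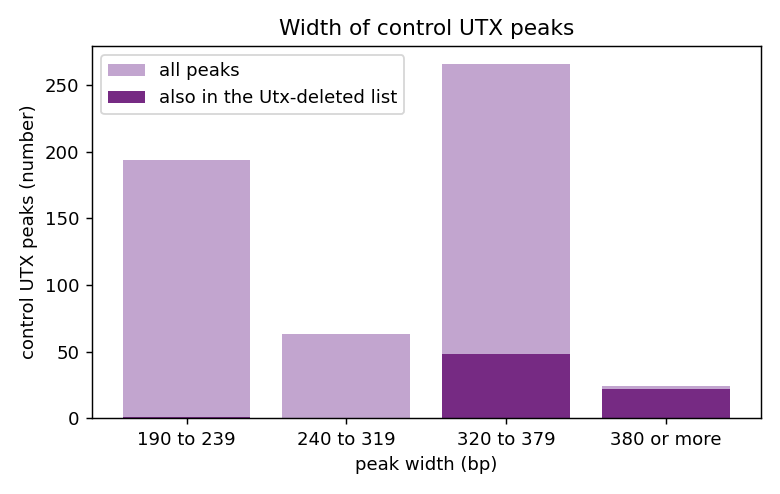
Number of control UTX peaks by peak width in bp (light bars) and the number that overlap a Utx-deleted UTX peak (dark bars). Of the peaks of 380 bp or more, 22 of 24 are shared.

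The peaks seen with the UTX antibody after deletion lay largely elsewhere. Chromosome 4 held 64 of the 213 against 12.5 expected (adjusted p = 5.974e-27) and chromosome 8 held 30 against 10.3 (adjusted p = 1.678e-06, exact binomial test). In the region from 145000001 to 148000000 of chromosome 4, which holds 27 protein-coding genes of which 16 are named Zfp, there were 60 Utx-deleted UTX peaks and 20 Utx-deleted H3K27ac peaks, and 0 peaks of either control list. Zfp982 had 9 UTX peaks, Gm42346 had 7 and Zfp978 had 6. The 5 windows with at least 5 such peaks per Mb, chosen on these peaks, held 114 of the 213 peaks. Outside them 99 Utx-deleted UTX peaks and 19 Utx-deleted H3K27ac peaks remained. Of the Utx-deleted UTX peaks 8.65% lay within 1 kb of a gene end, 3.04 times the random share (permutation p = 0.002, the smallest possible), and without the windows this ratio was 1.37 (p = 0.683).

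**Figure D4:**
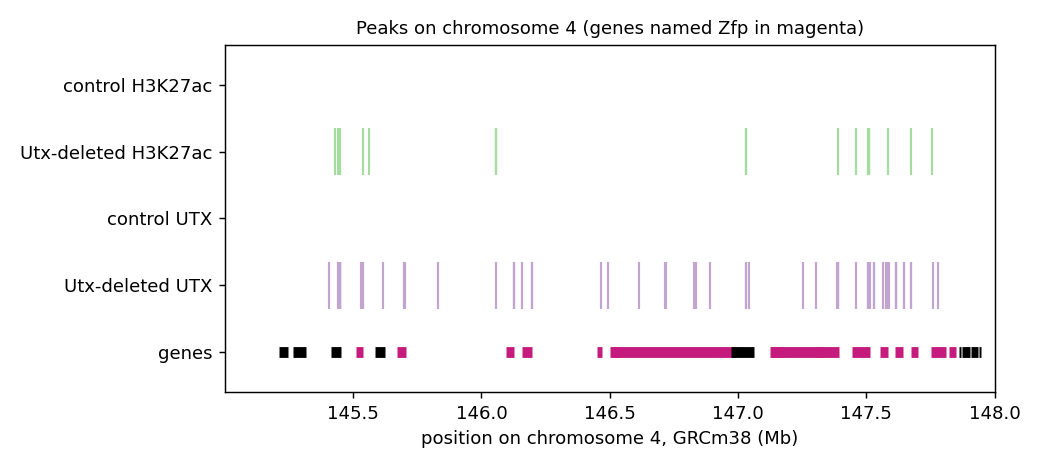
Position of peaks of the 4 lists (vertical lines) and of protein-coding genes (blocks, magenta for genes named Zfp) on chromosome 4, in Mb on GRCm38. The region holds 60 UTX and 20 H3K27ac peaks of Utx-deleted epidermis and 0 control peaks.

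The fourth comparison asks whether UTX peaks carry H3K27ac. In control epidermis 4 of 547 UTX peaks (0.731%, 0.285 to 1.86) overlapped an H3K27ac peak, against 0.305 at random (p = 0.001, one-sided permutation, the smallest possible). They were assigned to Acsl5, Arid1b, Dpp9 and N6amt1, of which the last pair was named after its values were seen. Those at Arid1b and Dpp9 also overlapped a Utx-deleted UTX peak, and without the peaks shared in this way, a setting chosen after seeing the data, 2 were left (permutation p = 0.027). At the level of genes, 50 had a peak in both control lists against 31.7 expected (odds ratio 1.66, adjusted p = 0.00304, Fisher's exact test), and genes matched on length, a comparison chosen after seeing the data, gave 37.3 (permutation p = 0.0432). Among them were Rfx5, with an H3K27ac peak of 683 bp, and Actn4, with one of 669 bp. The UTX and H3K27ac peaks of a gene need not lie together. Of the 547 control UTX peaks, 282 lay outside genes, at a median of 40592 bp from the assigned gene. Over the genes with a peak in any list the odds ratio was 0.00372, a background in which a gene without one peak nearly always has the other.

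In Utx-deleted epidermis most H3K27ac peaks lay on peaks of the UTX antibody, called UTX peaks here whether or not UTX is present. Most of these UTX peaks lay apart from H3K27ac peaks. By the numbers in their titles the libraries of both came from the same 3 animals, and random placement takes no account of chromatin they share. Of the 48 H3K27ac peaks, 35 (72.9%, 59.0 to 83.4) overlapped a UTX peak, against 0.003 at random (permutation p = 0.001, the smallest possible), and 34 of the 213 UTX peaks overlapped an H3K27ac peak. At Dock2, Cldn34d, Vps45, Snrpe and Frmd4a peaks of both antibodies overlapped. Of the 27 genes with an H3K27ac peak, 21 also had a UTX peak (expected 0.138, adjusted p = 9.179e-44, Fisher's exact test). Several of them are neighbouring Zfp genes on chromosome 4, which are not independent, so this p is too small. Without the 5 windows, 11 UTX peaks overlapped an H3K27ac peak.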

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

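Settings that drop the dense windows, merge peaks within 10 kb, move peaks together, drop shared UTX peaks or match genes with both control peaks on length were chosen after seeing the data. Of 165 alternative values over 49 results, 136 kept their direction, their side of the threshold and, for counts, a size within 1.5 times. The 136 include counts and odds ratios of 0 that stayed 0, which had little room to move. The wider peaks alone were those above the median width of both genotypes of an antibody together, so a fall in the joint number was built in. They came to 1068 control and 25 Utx-deleted H3K27ac peaks, and 288 control and 90 Utx-deleted UTX peaks. Of the wider UTX peaks, 43 were shared by genotypes, and 2 control and 19 Utx-deleted ones lay on wider H3K27ac peaks. Without the dense windows there were 19 Utx-deleted H3K27ac peaks, 99 Utx-deleted UTX peaks and 11 of these on H3K27ac, and the ratio to random near gene ends was 3.18 for Utx-deleted H3K27ac (p = 0.248) and 1.37 for Utx-deleted UTX (p = 0.683), by permutation. That ratio was 2.63 within 500 bp for Utx-deleted H3K27ac and 1.45 for Utx-deleted UTX with peaks within 10 kb merged, neither past the threshold. The cause was not tested. Without UTX peaks shared with the Utx-deleted list, 2 control UTX peaks lay on H3K27ac (permutation p = 0.027). The H3K27ac peak shared by genotypes stayed 1 within 1 kb, no longer past the threshold. The odds ratio of having both control peaks reversed to 0.00372 over genes with any peak, by construction. Other values turned direction without passing the threshold, and the cause was not tested: the control UTX ratio near gene ends (1.26 within 3 kb, 1.03 with merged peaks), the control H3K27ac odds ratios of wound genes (1.26 within 10 kb, 1.75 for wider peaks), retinoid genes (0.961 by nearest gene end) and endothelial, mural and muscle genes (0.988 within 10 kb), and UTX peaks on X over expectation (control 1.31 by gene number, Utx-deleted 0.651 with merged peaks, where the call was lost). Chromosomes that differ from expectation went from 0 to 2 for control UTX by gene number, and from 6 to 2 for Utx-deleted UTX with merged peaks. The q threshold and leaving out single libraries were not run, since the lists hold neither. No paired analysis was possible because each list merges its libraries.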

Other observations

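The overlaps between genotypes and their random placement were planned. All other tests in this part, and what each explanation would predict, were chosen after the results were seen. In control epidermis, H3K27ac peaks were also assigned to early response genes outside the AP-1 list. Of 36 immediate-early and NF-kB feedback genes, 19 had a peak, with 5 assigned to Dusp1, 4 to Pim1 and 3 to Nfkbia. The list was drawn up because some of its members had been seen among the genes with most peaks. Among the 31 members not used to choose it, 14 had a peak against 1.62 expected (adjusted p = 3.670e-10, Fisher's exact test). This list and those below were written after the peaks had been assigned to genes. Their p-values are therefore not an independent check and may be too small. Of 11 genes of the Skint family, which lie together on chromosome 4, 8 had a peak. Of the 9 members not used to choose the list, 6 had a peak against 0.471 expected (adjusted p = 2.227e-06, exact), but neighbouring genes are not independent. Circadian clock genes were chosen for Nr1d1 with 6 peaks and Per1 with 5, and with these 5 of 22 had a peak against 1.31 expected. Rora, with 2 peaks, had also been seen before. Of the 19 members left without these genes, 2 had a peak against 0.994 expected (adjusted p = 0.262, exact), too few to decide. Handling of the tissue before crosslinking was not tested as a source of the early response genes.

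The Utx-deleted lists crowd into 5 windows that make up 0.306% of the genome. Signal that does not depend on the antibody is a candidate explanation: 75.9% of the Utx-deleted H3K27ac peaks in the windows (22 of 29, 57.9 to 87.8; random mean 0.32 peaks) overlapped a UTX peak, as did 13 of the 19 outside them (68.4%, 46.0 to 84.6). A mapping artefact that gives peaks in both genotypes alike was not seen in the control UTX list, with 0.183% of its peaks there (upper bound 1.03%). This does not exclude one of equal size, since the windows were chosen on the Utx-deleted UTX peaks. A difference between the inputs could also hide it in control. Copy number or strain differences between the animals, and depth of the input libraries, stay open and were not tested.

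The 71 UTX peaks common to both genotypes exceed chance overlap, of which the highest random value was 1. Of the 71, 1 lay within 1 kb of a gene end, 3 overlapped an H3K27ac peak of either genotype and 0 lay in the windows. UTX left in cells that escaped deletion, and binding of the antibody to something other than UTX, stay open and were not tested. In the control list, 47 of the last 54 peaks in file order were shared, against 24 of the 493 earlier ones. In the Utx-deleted UTX list 21 of the last 21 were shared, against 50 of the 192 earlier ones. What sets the file order is not known.

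The Utx-deleted H3K27ac list is nearly empty. Lower recovery of acetylated DNA or shallower sequencing in the Utx-deleted libraries cannot be told apart from a loss of acetylation: 0 of the 214 widest control peaks remained and 1 of all 2140, too few to compare. Of 30 housekeeping genes, 10 had a control H3K27ac peak and 0 a Utx-deleted one (0.037 expected from the size of that list). With so few expected, this 0 follows from the size of the Utx-deleted list and cannot show which kinds of genes lost acetylation. Of the 48 Utx-deleted peaks, 35 overlapped a Utx-deleted UTX peak. The number of reads per library was not used here, and a biological effect of the deletion on acetylation stays open, as untested.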
